A study of Mus musculus with 4 samples.

How the data were processed

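Gene expression was measured in mouse embryonic stem (ES) cells on 4 cDNA microarrays with 2 colours each. Every array carried RNA from 1 mutant line and from wild-type cells. The mutants were fosBd/d, whose allele makes only the short form ΔFosB, and fosB-null. Each mutant had 2 arrays with the dyes exchanged (a dye swap). Per the series title, the cells had been starved of serum for 72 h and given serum for 4 h, and per the labels they were grown without feeder cells.

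The authors deposited 1 value per probe and array, taken here as the log10 ratio of the channels, as Agilent Feature Extraction defines its log ratio. That software is named in the submitters' processing notes. Its version, the background correction, the dye normalization and any filter are not given in the sources used here, and the log base rests on the software's definition. All values were multiplied by the log2 of 10 and are given as log2 ratios, so the scale of every fold change rests on that base. Signal and background intensities were not analysed here. The number of arrays limits the precision.

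Each column held 9480 values with a median of 0.00. The log2 SD was 0.824 and 0.652 on fosBd/d replicates 1 and 2, and 0.436 and 0.542 on fosB-null replicates 1 and 2. Probes were named from a platform annotation table of 2007, with symbols updated by gene identifier through a RefSeq gene table. Of the 9480 probes, 6566 had 1 gene, 392 had several and 2522 had none listed. Identifiers matched for 6496 of the 1-gene probes, and 70 kept the older name. The named probes covered 6025 genes. For the 502 genes with several probes, the correlation across genes between the first and second probe was 0.159 for fosBd/d and 0.245 for fosB-null.

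The direction of the ratios was not settled. Exact zeros were written with a minus sign on fosBd/d replicate 1 (960 values) and fosB-null replicate 2 (551 values), and without one on fosBd/d replicate 2 (423 values) and fosB-null replicate 1 (478 values). Those marks are what multiplication by -1 leaves, so each swap appears to have been turned to run one way before deposit, and the values were used as they stood. Arrays labelled with the mutant in the same dye nevertheless correlated negatively across probes, with r = -0.463 for replicate 1 of both mutants and r = -0.369 for replicate 2 of both. With the apparent turning undone, all 6 pairs of arrays correlated positively. Read by the dye names (Cy5 over Cy3), a positive fosBd/d value means more RNA in the mutant, and a positive fosB-null value means less. A single mutant-over-wild-type convention for all arrays gives the same reading for fosBd/d and the opposite one for fosB-null. The labels also call Cy3 red and Cy5 green, and that reading turns fosBd/d. A positive fosBd/d value is therefore called likely higher in the mutant, and fosB-null values are given by sign only. Comparisons between the mutants are given as deposited and with the fosB-null sign turned. Read by the colour words, fosBd/d is turned and fosB-null is not, which reverses every difference given with the fosB-null sign turned.

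The main test was a linear model in limma 3.58.1 (R 4.3.3) on all 4 arrays, with a coefficient per mutant and a dye term for each probe, which left 1 residual degree of freedom before empirical Bayes moderation. The estimated prior had 1.33 degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels do not say whether the 2 arrays of a swap used the same RNA extracts. The limma p-values for single probes therefore measure only the spread between arrays, which may be technical. A size rule without a test counted probes that were at least 2-fold the same way on both arrays of a swap, beside the number 2-fold in the dye direction.

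On simulated data with 200 of 9480 probes changed in the fosBd/d comparison and noise drawn from the fitted prior, the limma step recovered 0% of 2-fold changes, 0% of 4-fold changes and 19.0% of 8-fold changes. The 2-fold rule recovered 14.0%, 90.0% and 96.9% of them, but also took 146, 145 and 141 unchanged probes. With a noise variance of 0.001, against a fitted prior variance of 0.0285, limma recovered 100% at each size and took 8.80 to 9.60 unchanged probes, and the 2-fold rule took 0.

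Gene lists were written before the data were examined and tested with camera (limma, preset correlation 0.01) on probes averaged per gene, for lists with at least 5 measured genes. They covered endoderm, basement membrane, other extracellular matrix, integrins and focal adhesion, actin and contractile genes, serum early response, AP-1 subunits, TGF-β signalling, proteases and their inhibitors, pluripotency, mesoderm, neural and ectoderm, trophoblast, feeder fibroblasts, cell cycle, p53 targets, stress and chaperones, glycolysis and hypoxia, sterol synthesis, interferon response, ribosomal proteins and imprinted genes. A list of Y-linked and X inactivation genes had 3 measured genes and was not tested. Basement membrane and TGF-β lists were included because the study is known for these groups. Camera set the statistics of a list's genes against those of the other genes. With the preset correlation its p-values measure the spread over genes, not between cultures. Camera with an estimated correlation rested on 1 residual degree of freedom. It called 0 of the shifted lists simulated next, so its adjusted p values do not count for or against a list. In 100 simulations of a 20-gene list shifted by 1 log2 unit, the preset correlation called all 100 and the estimated correlation called 0. An unshifted list was called 3 times with the preset correlation. Calls were made at an unadjusted camera p under 0.05. The simulated noise was independent between genes, so false calls of the preset correlation for lists of co-regulated genes were not tested.

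The genes named were fixed by a rule. For each mutant these were up to 10 genes with the highest and 10 with the lowest mean among probes past the threshold, filled up from probes at least 1.5-fold the same way on both arrays, and 5 per side for the difference between mutants, for which fosBd/d replicate 1 was set against fosB-null replicate 2 and the reverse, pairs that share a dye direction as deposited. Up to 4 members of each list with the smallest p and all AP-1 subunits could be named too. Probes with several genes or none were not named. No probe was annotated to Fosb, so the targeted gene could not be used to check the labels. Alternatives covered the dye term, centring, scaling, exact zeros, averaging of probes, robust moderation, a minimum fold change and leaving out each array. Fits that left out an array also had no dye term.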

Results

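The data set held 4 arrays with 9480 probes each, 2 for fosBd/d and 2 for fosB-null ES cells, all against wild-type ES cells (pluripotent cells of the early embryo). FosB is a subunit of the AP-1 transcription factor, which serum induces, and ΔFosB is its truncated form. The comparisons ask how RNA levels differ from wild type when only ΔFosB is made, when no FosB protein is made, and between these mutants. Values are mean log2 ratios ± SD (n = 2 arrays).

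In fosBd/d cells, genes of the extraembryonic endoderm and of the basement membrane it secretes lay on the positive side, likely higher in the mutant. The collagen IV chains Col4a2 and Col4a1 had ratios of 2.57 ± 0.56 and 2.48 ± 0.25, which are 5.95-fold and 5.59-fold. The laminin chain Lamb1 stood at 2.46 ± 0.39, and F3 (tissue factor, which starts blood clotting) had the highest mean, 2.94 ± 0.11 or 7.67-fold. Over the 35 endoderm genes measured, the median was 1.42 with quartiles of 0.54 and 1.81, and 26 were positive on both arrays against 1 that was negative on both. The endoderm list passed camera with an adjusted p of 1.63e-14. This p measures the spread over genes, so it does not show that the shift would recur in another culture. With 1 residual degree of freedom the call was lost, adjusted p = 0.549 with an estimated correlation. That setting called 0 of 100 simulated shifted lists, so it could not decide.

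**Figure D1:**
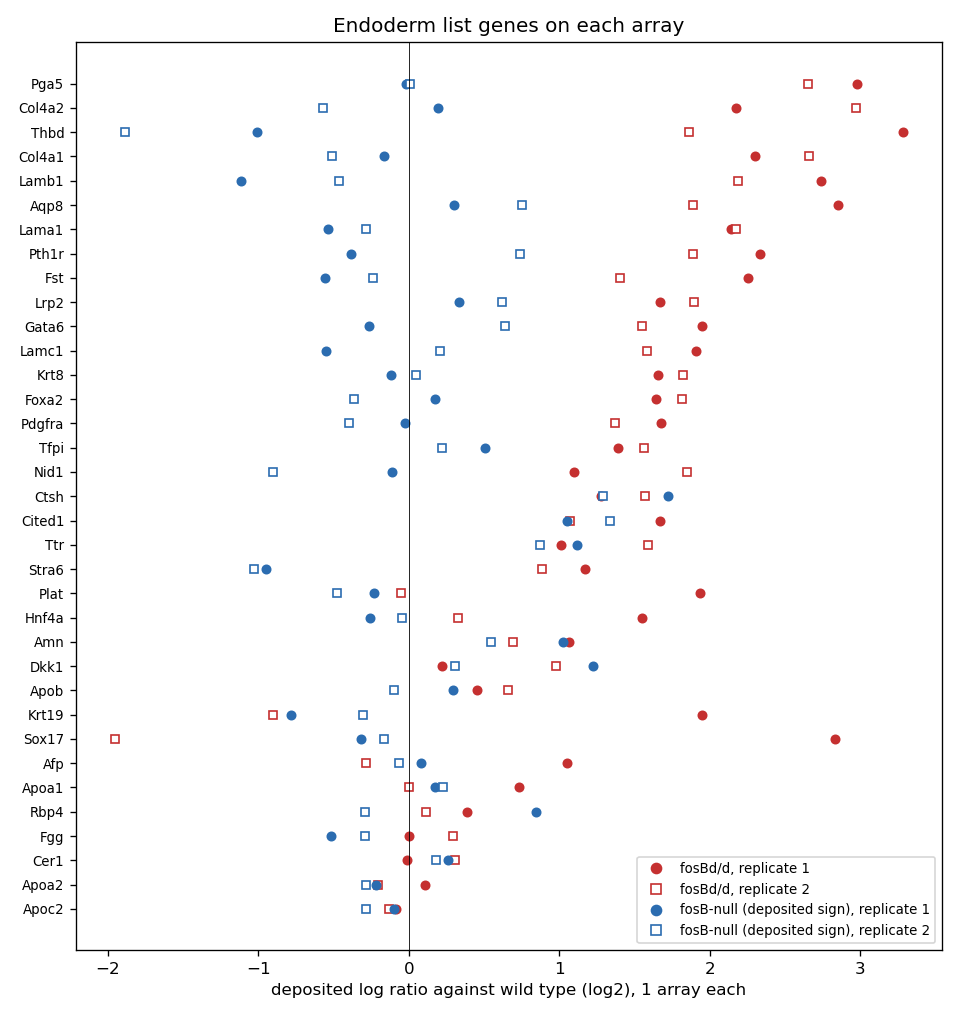
Deposited log2 ratios of the 35 measured endoderm genes, 1 point per array, in fosBd/d (red) and fosB-null (blue), with filled circles for replicate 1 and open squares for replicate 2. In fosBd/d, 26 genes were positive on both arrays, and Sox17 stood at 2.83 on one and -1.95 on the other.

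Some members of the endoderm list were chosen after their values were seen. Gata6, a regulator of primitive endoderm fate, stood at 1.75 ± 0.28, Foxa2 at 1.73 ± 0.12, the parathyroid hormone receptor Pth1r at 2.11 ± 0.32 and Pdgfra at 1.52 ± 0.22. The transcription factors Hnf4a and Sox17 differed between arrays, with 1.55 and 0.33 for Hnf4a and 2.83 and -1.95 for Sox17. Adjusted over the list alone, 24 of the 35 endoderm genes passed, and 0 passed over all genes.

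The basement membrane list had a median of 0.54 over 19 genes, with 15 positive and 2 negative on both arrays, and passed camera with an adjusted p of 1.40e-06. The call was lost, adjusted p = 0.549 with an estimated correlation. Adjusted over the list alone, 10 of the 19 passed. This list was chosen knowing the study and is not independent evidence. It shared 6 genes with the endoderm list. Without the shared genes, medians were 0.35 for basement membrane (13 genes, camera adjusted p = 0.0146) and 1.03 for endoderm (29 genes, adjusted p = 2.92e-10), and both had an adjusted p = 0.549 with an estimated correlation. Lama1 stood at 2.15 ± 0.02, while Col18a1 was at -0.24 ± 0.01.

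Serum early response genes, which follow growth factor signalling, shifted to the positive side with a median of 0.35 over 28 genes (camera adjusted p = 3.34e-04). Ccn1, a secreted matrix protein, stood at 1.45 ± 0.10, the urokinase receptor Plaur at 1.42 ± 0.34 and Rhob at 1.14 ± 0.51. Genes of actin and contraction (median 0.34, 24 genes, adjusted p = 8.46e-04), glycolysis and hypoxia (0.45, 17 genes, 0.00438), integrins and focal adhesion (0.40, 21 genes, 0.0182) and sterol synthesis (0.43, 11 genes, 0.0146) also passed camera. Among them were Anxa5 at 1.14 ± 0.20, the prolyl hydroxylases P4ha2 and P4ha1 at 1.93 ± 0.14 and 1.75 ± 0.14, Zyx at 1.09 ± 0.01 and Scd1 at 0.86 ± 0.54. The smooth muscle actin Acta2 disagreed between arrays, with 1.42 and 0.01. The cell cycle list lay on the negative side (median -0.14, 39 genes, adjusted p = 0.0173), with Ccnb2 at -0.61 ± 0.09 and Cdk1 at -0.50 ± 0.22, while Ccnd2 stood at 1.95 ± 0.48. All of these had an adjusted p = 0.549 with an estimated correlation. Without fosBd/d replicate 1, actin (0.614), glycolysis (0.418), integrins (0.418), sterol (0.242) and cell cycle (0.383) no longer passed, whereas endoderm, basement membrane and serum early response did. Without replicate 2, sterol (0.136) and cell cycle (0.308) did not pass, and cell cycle was at 0.0543 without either fosB-null array.

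The other lists did not pass camera in fosBd/d. Medians were 0.14 for proteases and inhibitors (adjusted p = 0.0711), 0.12 for AP-1 subunits (0.118), 0.12 for feeder fibroblast markers (0.115), 0.09 for other matrix genes (0.168), 0.07 for TGF-β signalling (0.150), 0.03 for p53 targets (0.872) and 0.03 for stress and chaperones (0.542). They were -0.01 for trophoblast (0.560), -0.08 for mesoderm (0.963), -0.10 for imprinted genes (0.963), -0.10 for neural and ectoderm (0.751), -0.15 for ribosomal proteins (0.0691), -0.24 for pluripotency (0.150) and -0.26 for interferon response (0.237). For imprinted genes and trophoblast the mean (0.08 and 0.17) and test were positive although the median was not, and for p53 targets the test was negative. Of the 7 AP-1 subunits measured, Jund stood at 0.50 ± 0.07 and Fos at 0.47 ± 0.50, and Maff, Atf2, Junb, Atf4 and Maf lay between 0.29 and -0.08. Of the 11 pluripotency genes, 5 were negative and 2 positive on both arrays, with Alpl and Nr5a2 at -0.79 ± 0.21 and -0.82 ± 0.16 but Utf1 and Lin28a at 0.45 ± 0.27 and 0.39 ± 0.05.

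**Figure D2:**
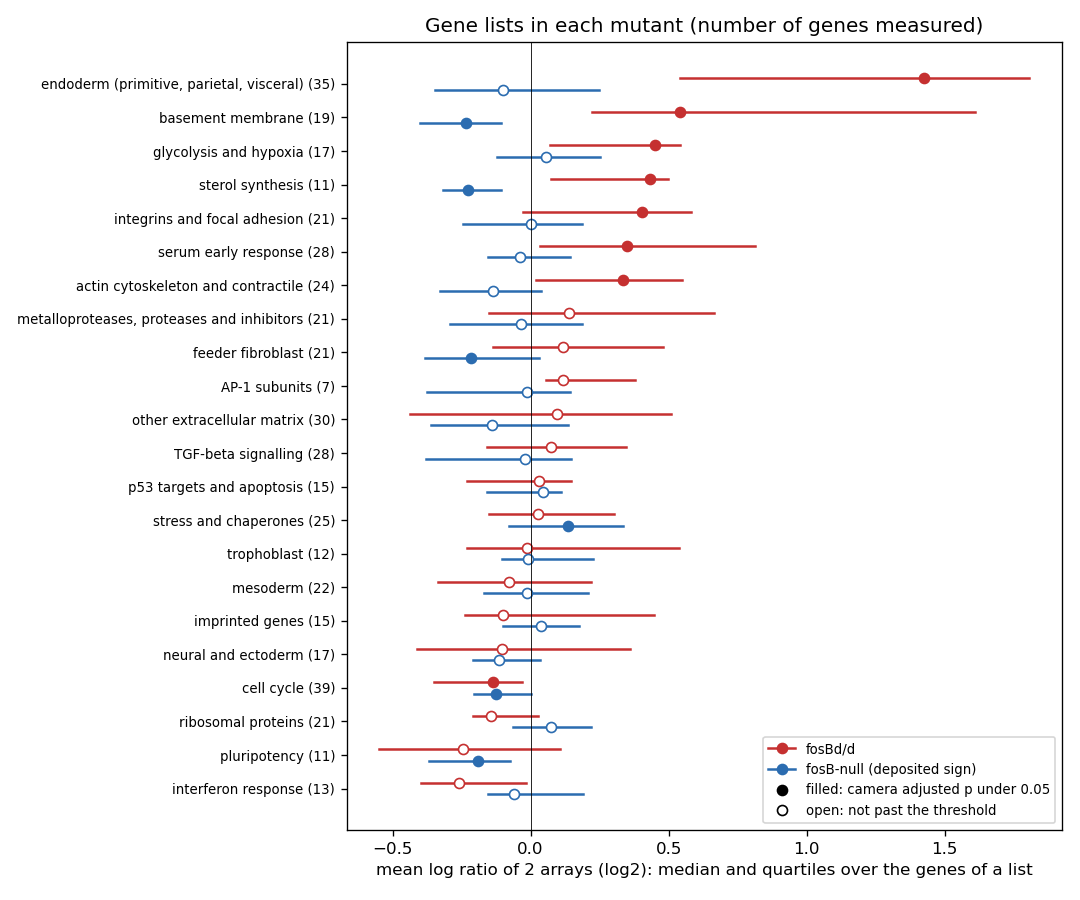
Median and quartiles of the mean log2 ratio over the genes of each of 22 lists in fosBd/d (red) and fosB-null (blue, deposited sign), with filled points where camera passed. The endoderm list had a median of 1.42 in fosBd/d and -0.10 in fosB-null.

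Single probes did not pass limma in fosBd/d. The count was 0 of 9480 at an adjusted p under 0.05, with the smallest adjusted p at 0.297. In the dye direction of the same fit, 2151 probes had an unadjusted p under 0.05. For fosBd/d the number was 1503 (932 positive, 571 negative), where 474 would be expected by chance. That count fell to 709 without the dye term, to 813 and 973 without fosBd/d replicates 1 and 2, and to 351, below the chance number, without either fosB-null array. The fits that left out an array also had no dye term, so their counts are to be set against 709. By size, 150 probes were at least 2-fold the same way on both arrays, 118 positive and 32 negative, beside 273 in the dye direction. By the mean of both arrays the balance was the other way, with 215 positive and 305 negative at 2-fold and 685 and 923 at 1.5-fold. A residual contrast with no group effect, scaled to the same variance, had 162 probes at 2-fold and 729 at 1.5-fold. Simulated fosBd/d data with noise drawn from the fitted prior took 141 to 146 unchanged probes of either sign at 2-fold on both arrays. That prior was fitted on all arrays together, and fosB-null had only 23 probes by this rule. The simulated noise may be too heavy, so it cannot decide whether the 150 arose by chance. With each probe's own moderated variance and no effect, 10.8 positive probes were taken. Where a shared wild-type extract and a mutant extract each added the variance of an array, 141 were taken, against the 118 observed. Extract differences could thus give a count of this size, although that run took 139 in fosB-null, where 15 were observed. Whether they did was not tested. Among probes with 1 gene, 117 were observed (100 positive, 17 negative), beside 73 in the dye direction. The positive end also held Pga5 (2.81 ± 0.23), the phosphate transporter Slc34a2 (2.64 ± 0.42), thrombomodulin Thbd (2.57 ± 1.00), Sprr2a1 (2.42 ± 0.78), Nfia (2.42 ± 0.31, with its other probes at 0.45 and -0.62) and Ap1m2 (2.40 ± 1.65). The negative end held Fibin (-2.77 ± 2.84), Angptl7 (-2.14 ± 0.38), A630023P12Rik (-2.07 ± 1.78), Cacng4 (-2.04 ± 1.33), Atp8a2 (-1.97 ± 1.00), Pnoc (-1.94 ± 1.15), Slc27a2 (-1.79 ± 0.17), Bmerb1 (-1.73 ± 1.18), the apoptosis regulator Bad (-1.72 ± 0.23) and Wdr13 (-1.70 ± 0.92).

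In fosB-null cells the direction of the ratio is open. Basement membrane genes lay on the negative side with a median of -0.23 over 19 genes (camera adjusted p = 2.06e-04), with 9 negative and 1 positive on both arrays. Lamb1 stood at -0.79 ± 0.46 and Nid1 at -0.51 ± 0.56. Sterol synthesis (-0.23, 11 genes, adjusted p = 0.00659), feeder fibroblast markers (-0.22, 21 genes, 0.0217), cell cycle (-0.13, 39 genes, 0.0284) and pluripotency (-0.19, 11 genes, 0.0284) were also negative, and stress and chaperones were positive (0.14, 25 genes, 0.0284). Examples were Ebp (-0.58 ± 0.01), Tnc (-0.85 ± 0.03), Col1a2 (-0.73 ± 0.05), Mki67 (-0.42 ± 0.19), Dppa2 (-0.50 ± 0.28) and Hspa1a (0.58 ± 0.69). With an estimated correlation these calls were lost, adjusted p = 0.835 for pluripotency and 0.787 for the others. That setting called 0 of 100 simulated shifted lists, so it could not decide. Adjusted over the list alone, 0 basement membrane genes passed, and that list is not independent evidence.

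Without fosB-null replicate 1, 0 lists passed (basement membrane adjusted p = 0.202), and without replicate 2, 3 lists passed, among them basement membrane and stress and chaperones. Cell cycle was also lost without the dye term (0.0679), and stress and chaperones with the rank-based test (0.0821). The fits that left out an array had no dye term either. With the sign turned, each of these shifts would read the other way.

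The other lists did not pass in fosB-null. Medians were -0.14 for actin and contraction (adjusted p = 0.0821), -0.14 for other matrix genes (0.0683), -0.11 for neural and ectoderm (0.341), -0.10 for endoderm (0.923), -0.06 for interferon response (0.692), -0.04 for serum early response (0.754), -0.03 for proteases and inhibitors (0.923), -0.02 for TGF-β signalling (0.457), -0.01 for mesoderm (0.565), -0.01 for AP-1 subunits (0.544) and -0.01 for trophoblast (0.719). They were 0.00 for integrins (0.987), 0.04 for imprinted genes (0.754), 0.04 for p53 targets (0.923), 0.06 for glycolysis and hypoxia (0.544) and 0.07 for ribosomal proteins (0.225). Median and mean differed in sign for endoderm (mean 0.0011), integrins, interferon response, proteases, p53 targets and trophoblast.

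In limma, 0 of 9480 probes passed in fosB-null, the smallest adjusted p was 0.651, and 578 probes had an unadjusted p under 0.05 (280 positive, 298 negative). That count was 179 without the dye term, 176 without either fosBd/d array, 179 without fosB-null replicate 1 and 46 without fosB-null replicate 2. The fits that left out an array had no dye term either, so their counts are to be set against 179. By size, 23 probes were at least 2-fold on both arrays, 15 positive and 8 negative, beside 142 in the dye direction. Simulated unchanged arrays gave 10.8 positive probes with each probe's own moderated variance. By the mean of both arrays, 53 were positive and 36 negative, a total of 89 against 162 in the residual contrast. Among probes with 1 gene the numbers were 18 and 13. The homeobox genes Hoxa10 (3.15 ± 0.11) and Hoxa11 (1.49 ± 0.26) were on the positive side with Atp8a2 (2.05 ± 0.23), Clec4f (1.62 ± 0.02), Cxcl15 (1.61 ± 0.14), Bves (1.54 ± 0.34, other probe 0.43), cathepsin H Ctsh (2.83-fold, log2 SD 0.31), Amn (1.46 ± 0.02, other probe 0.11), Spink1 (1.31 ± 0.30) and Mgrn1 (1.29 ± 0.33). The negative side held BC147527 (-2.00 ± 0.08), the Y-linked Eif2s3y (-1.68 ± 0.35), Thbd (-1.45 ± 0.62), Guca1a (-1.23 ± 0.53), Pla2g1b (-1.16 ± 0.23), thrombospondin Thbs1 (-1.14 ± 0.52), Crmp1 (-1.10 ± 0.06), Abcb1a (-1.10 ± 0.26), the AP-1 partner Atf2 (-1.03 ± 0.26) and Stra6 (-0.99 ± 0.06).

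**Figure D3:**
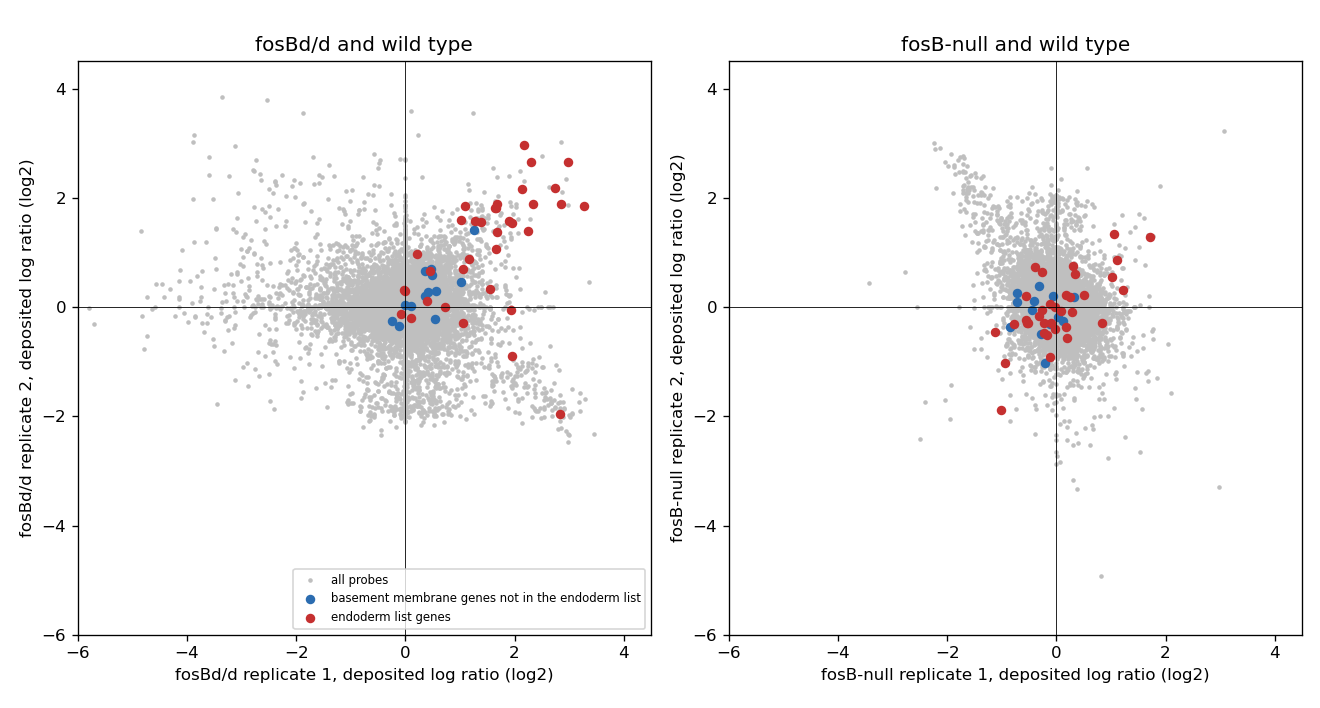
Deposited log2 ratios of all 9480 probes on replicate 1 against replicate 2, for fosBd/d (left) and fosB-null (right), with endoderm genes in red and basement membrane genes outside that list in blue. The fosBd/d endoderm genes lie mostly at the upper right, where 118 probes were at least 2-fold positive on both arrays.

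Between the mutants, the endoderm list had the highest median difference of the 22 lists, with fosBd/d above fosB-null by a median of 1.29 (camera adjusted p = 6.04e-10). With the fosB-null sign turned, the median was 1.43 (adjusted p = 9.78e-14). Read by the colour words this median would have the other sign, with fosBd/d below fosB-null. As deposited, basement membrane (0.89, adjusted p = 8.40e-08), serum early response (0.51, 0.00169) and actin and contraction (0.45, 7.67e-04) also passed. Basement membrane shares 6 genes with the endoderm list, and the difference was not tested without them. With the sign turned their medians were 0.47 (adjusted p = 6.32e-04), 0.36 (5.62e-04) and 0.31 (0.0144), so 6 lists passed as deposited and 9 with the sign turned. Sterol synthesis and feeder fibroblast markers passed only as deposited and had adjusted p values of 0.510 and 0.786 with the sign turned. Only with the sign turned, glycolysis and hypoxia (median 0.54, adjusted p = 5.62e-04), integrins (0.43, 0.0144) and stress and chaperones (0.25, 0.0164) passed on the positive side, and cell cycle (-0.27, 6.32e-04) and pluripotency (-0.58, 0.0120) on the negative side. As deposited the calls were lost, adjusted p = 0.578 with an estimated correlation, and with the sign turned the smallest such value was 0.640. As deposited, the actin list did not pass without fosBd/d replicate 1 (0.413) or without fosB-null replicate 1 (0.109), and feeder markers did not pass without replicate 2 of fosBd/d (0.158) or of fosB-null (0.102). With the sign turned, 3 lists passed without fosBd/d replicate 1 (endoderm, basement membrane and serum early response), and the actin list then lay on the negative side (0.910). Without fosBd/d replicate 2, cell cycle (0.0942) and stress (0.290) did not pass, without fosB-null replicate 1 stress (0.414) did not, and without fosB-null replicate 2 actin (0.804), glycolysis (0.0713) and integrins (0.296) did not. Without the dye term, which the fits without an array also lacked, actin (0.0801) and stress (0.0539) did not pass.

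Differences are given ± SE from the spread within each mutant (2 arrays each, with no arrays paired). As deposited, the highest were in Thbd (4.02 ± 0.83), F3 (3.62 ± 0.14), Lamb1 (3.25 ± 0.43), Ap1m2 (3.16 ± 1.204) and Nfia (2.94 ± 0.30), and the lowest in Hoxa10 (-4.39 ± 1.25), Atp8a2 (-4.03 ± 0.72), Sycp3 (-3.61 ± 2.71), Bves (-3.41 ± 1.71) and Cxcl15 (-3.34 ± 2.21). These values rest on 1 probe per gene, and other probes stood at 0.40 and -0.71 for Nfia and at -1.65 for Bves. Hoxa10 was listed at exactly 0 on fosBd/d replicate 2, beside -2.49 on replicate 1. These ranks did not hold with the fosB-null sign turned, where Thbd stood at 1.13, F3 at 2.26, Lamb1 at 1.67, Ap1m2 at 1.64, Nfia at 1.89, Hoxa10 at 1.90, Atp8a2 at 0.08, Sycp3 at -2.41, Bves at -0.34 and Cxcl15 at -0.12. Ranked that way, the highest were Spink1 (2.94 ± 0.33), Ctsh (2.93 ± 0.26), Amn (2.90 ± 0.02, other probe 0.43), Aqp8 (2.89 ± 0.53) and Pga5 (2.81 ± 0.16), and the lowest Eif2s3y (-2.78 ± 0.47), Angptl7 (-2.52 ± 0.31), Fibin (-2.50 ± 2.08), Cav3 (-2.30 ± 0.47) and Cacng4 (-2.23 ± 0.99). With the arrays paired by replicate number, Siah1a (-2.08) took the place of Fibin in that ranking. In limma, 0 of 9480 probes passed (smallest adjusted p 0.357, 1320 with an unadjusted p under 0.05), and 0 passed with the sign turned (0.524 and 865). Fits that left out an array also had no dye term. The 1320 fell to 539 without the dye term, to 692 and 827 without fosBd/d replicates 1 and 2, and to 260 and 149, below the chance number, without fosB-null replicates 1 and 2.

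Some genes were at least 2-fold in both mutants. As deposited, Spink1, Ctsh, Amn and Cited1 were positive in both and 0 probes were negative in both, while Thbd was positive in fosBd/d and negative in fosB-null and Atp8a2 was the reverse. With the fosB-null sign turned, Spink1, Ctsh, Amn and Cited1 would point opposite ways in the mutants, and Thbd and Atp8a2 the same way. Independent lists would share 0.187 positive probes. Simulated unchanged mutants, with both ratios taken as mutant over wild type, shared 0.290 with array noise alone. They shared 35.5 where a shared wild-type extract and separate mutant extracts each added the variance of an array. That last simulation took 141 positive probes in fosBd/d, against 118 observed, and 139 in fosB-null, against 15 observed. In opposite directions it shared 3.7 (fosBd/d positive) and 3.53 (fosBd/d negative), against 0.41 and 0.3 with array noise alone. If the fosB-null ratio is wild type over mutant, same-direction and opposite-direction values change places. Across all probes, which are not independent replicates, the mutants' mean ratios correlated at r = -0.0950 (covariance -0.0135), or 0.0950 with the fosB-null sign turned. Simulated unchanged mutants gave r = -0.000203 with array noise alone. They gave 0.401 (covariance 0.102) where a shared wild-type extract and separate mutant extracts each added the variance of an array. These values took both ratios as mutant over wild type. If the fosB-null ratio is wild type over mutant, the shared-extract value to set beside the deposited -0.0950 is -0.401. Part of any correlation may come from the shared wild-type RNA.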

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

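The comparison of different probes of 1 gene was chosen before its value was seen, the interval of its difference was added afterwards, and the other 4 tests of explanations given here were chosen only after the result was seen.

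The mutants' shifts from wild type differed for 4 gene lists by a camera test of the difference itself, with the fosB-null sign as deposited and turned. These are not 4 separate results, since endoderm and basement membrane share 6 genes and the difference was not tested without them. The basement membrane list was also chosen knowing the study. The median difference was 1.29 for endoderm, 0.89 for basement membrane, 0.51 for serum early response and 0.45 for actin and contractile genes as deposited, and 1.43, 0.47, 0.36 and 0.31 with the sign turned. Read by the colour words, the values with the sign turned would be negative, so the direction stays open. The actin list did not pass without fosBd/d replicate 1 with either sign (adjusted p = 0.413 as deposited and 0.910 turned). None of the 4 passed when the correlation was estimated from the data, which rested on 1 residual degree of freedom. That setting called 0 of 100 simulated shifted lists, so it could not decide.

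Arrays labelled with the same orientation correlated negatively, at -0.463 and -0.369. Opposite genotype effects in values that nobody turned would leave shared dye bias in the mean of each swap, and the means correlated at -0.0950, which argues against it. Dye bias belonging to each probe, carried with a turned sign by 2 arrays, may explain the pattern but was not decided. The dye-direction parts of the 2 swaps correlated at r = 0.609 across probes, as shared dye bias would give. Over probes with 1 gene the value was 0.480. Both values are built from the same array values as the pattern, so they are not a separate test. Different probes of 1 gene correlated at 0.0535 in the dye direction against 0.159 in the fosBd/d mean and 0.245 in the fosB-null mean. Over resampled genes the difference had a 95% interval of -0.0239 to 0.237 for fosBd/d, which includes 0, and 0.0675 to 0.318 for fosB-null. Whether the labels or the turning of 1 swap were crossed was not tested and stays open.

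The endoderm list was positive in fosBd/d. A fault of replicate 1 alone is argued against by replicate 2, where the list's median was 1.40 with a lower quartile of 0.30. RNA from feeder fibroblasts is argued against by 19 feeder markers outside the endoderm and basement membrane lists, with a median of 0.0720 and an upper quartile of 0.45, below the endoderm list's lower quartile of 0.54, and per the labels the cells were grown without feeders. A larger share of endoderm-like cells in the culture could also raise this list, and it cannot be told apart from a change within the cells in RNA from a whole culture, since the pluripotency list had a median of -0.24 that did not pass camera. The genotype itself, and differences between cell lines that do not come from FosB, stay open and untested.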

How the results depend on the processing

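The alternatives that turned the fosB-null sign, paired arrays by replicate number, centred on values other than 0, subtracted the dye term, left out shared list members, tested lists on probes without exact zeros or applied the 2-fold rule to 1 array were chosen after seeing the data. In all alternatives, 0 probes passed in any comparison, with smallest adjusted p values from 0.195 to 0.891 for fosBd/d, 0.572 to 1 for fosB-null and 0.275 to 0.971 for their difference. In simulations with noise from the fitted prior, the main fit recovered 0% of 2-fold and 4-fold changes. A count of 0 was thus likely even with real changes, and its repeat does not show stability. Centring on the median moved nothing, because every array's median was 0. The counts of 150 (fosBd/d) and 23 (fosB-null) probes at least 2-fold became 445 and 103 at 1.5-fold, and 520 and 89 by the mean of both arrays. They were 114 and 30 with the arrays centred and scaled, and 241 and 36 with the dye term subtracted. The 1.5-fold and mean counts follow from the looser rule, and for the dye term the cause was not tested. Scaling also moved the number with an unadjusted p under 0.05 from 1503 to 1178 in fosBd/d and from 578 to 706 in fosB-null. Part of the gap between the mutants thus depended on the spread of whole arrays. On 1 array alone the 2-fold counts ranged from 1117 to 1382 and from 328 to 619, since a single array needs no agreement. The correlation of the mutants, -0.0950, reversed to 0.0950 with the fosB-null sign turned, by construction, and to 0.336 (fosBd/d replicate 1 with fosB-null replicate 2) and 0.326 (the other pair) over arrays that share a dye direction as deposited. With an estimated correlation 0 lists passed, against 8 for fosBd/d, 6 for fosB-null and 6 for their difference. That setting also called 0 of 100 simulated shifted lists, so it could not decide. Leaving out 1 array gave 3 to 8 lists for fosBd/d, 0 to 6 for fosB-null and 6 to 8 for the difference; the lone array of a mutant was then assumed to vary like the others. The endoderm, basement membrane and serum early response lists passed in fosBd/d under each of 9 other settings besides the estimated correlation. These were not 9 separate checks. Centring on the median repeated the main fit, and leaving out either fosB-null array gave the same fosBd/d values. Of 891 alternatives for single genes and lists, 825 kept their direction and side of the threshold, 60 kept the direction only and 6 reversed, each of these in the difference between mutants with the fosB-null sign turned. They were Hoxa10 (1.90), Atp8a2 (0.0786), the actin list without fosBd/d replicate 1 (adjusted p = 0.910) and the feeder list without fosBd/d replicate 2 (0.593), without fosB-null replicate 1 (0.677) and without the dye term (0.775). Turned values of the fosB-null ratios themselves, which reverse by construction, are not among the 891. The single genes were chosen for at least 1.5-fold the same way on both arrays or array pairs, and 0 probes passed in any setting. Many of the 825 were therefore fixed in advance, and their number does not measure stability. With the sign turned, leaving out 1 array gave 3 to 8 lists for the difference. Signal over background was not analysed here.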

Other observations

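The genes in these paragraphs were chosen after their values were seen, apart from members named by the rule fixed beforehand, and no test of an explanation was run on them.

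In fosBd/d the lysyl hydroxylases Plod1 and Plod3 had log2 ratios of 1.47 ± 0.52 and 1.05 ± 0.29 (SD, n = 2 arrays), and the chaperone Hspa5 stood at 0.95 ± 0.18. Single genes elsewhere had ratios of similar size: the imprinted growth factor gene Igf2 at 1.17 ± 0.36, the transcription factor Snai1 at 1.71 ± 0.04 and the homeobox gene Gbx2 at -1.63 ± 0.39. The mesoderm and neural lists that hold Snai1 and Gbx2 did not pass camera.

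Of the 35 members of the endoderm list, 10 were positive and 15 negative on both fosB-null arrays. The list did not pass camera (adjusted p = 0.923). Ctsh was 2.83-fold on the positive side, and Cited1 and Ttr stood at 1.19 ± 0.20 and 0.99 ± 0.17, the same sign as in fosBd/d (1.42, 1.37 and 1.30). Lamb1, Stra6 and Thbd stood at -0.79, -0.99 and -1.45, against 2.46, 1.03 and 2.57 in fosBd/d. With the fosB-null sign turned, the first set would oppose fosBd/d and the second would match it.

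Eif2s3y, on the Y chromosome, was negative on all 4 arrays, with means of -1.10 ± 0.57 in fosBd/d and -1.68 ± 0.35 in fosB-null, while the X inactivation RNA Xist stood at -0.28 ± 0.34 and 0.19 ± 0.12. Kdm5d, also Y-linked, was listed at exactly 0 on 3 of its 4 arrays. Medians by chromosome, over the 20 chromosomes with at least 173 named probes, lay between -0.06 and 0.04 in fosBd/d and between -0.03 and 0.05 in fosB-null.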
